A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

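RNA was measured on 8 Illumina bead arrays, 5 hybridised with RNA from mouse thymus and 3 with RNA from H1299 cells, a human lung cancer line that lacks p53. Per the labels, RNA was extracted with Trizol and labelled with biotin by the standard Illumina protocol. The mice were of the CD-1 background and 2.5 weeks old. Per the labels, irradiated mice received 15 Gy and were treated for 10 h. Groups were taken from the sample labels: 1 unirradiated wild-type array, 2 irradiated wild-type arrays, 2 irradiated arrays labelled TRAF6 null, and 1 H1299 array each for vector, p53 wild type and p53 K24R. The labels do not say whether the 2 arrays of a group came from separate animals, so p-values measure the spread between these samples. For H1299 there was no replicate, so no test was run and no p-value is given.

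The deposited non-normalized tables hold, per the file headers, the mean bead signal as a linear intensity, its bead standard error, the number of beads and a detection p-value per row and array. The mouse table has 30854 rows with 1 row per gene symbol, so probes of a gene, and with them the detection p-values, had been averaged before deposit. The human table has 47323 probes of 34694 genes. The authors' series matrix holds the same intensities multiplied by 1 constant per array, as a comparison of the tables showed. The constants were 0.899, 1, 1.04, 0.925 and 0.956 for the mouse arrays in the order of groups above, and 1.02, 1.01 and 1.06 for vector, p53 wild type and K24R. The medians of the matrix columns were 102.4, 116.8, 119.7, 103.9 and 110.3 for mouse and 117.5, 118.5 and 123.5 for H1299. The matrix values are linear, neither background-subtracted nor centred. For H1299 they are means over a gene's probes. How the constants were chosen is not stated in the labels or headers.

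Median bead numbers per row were 41 to 43 on the mouse arrays and 21 to 22 on the human arrays, and the typical bead standard error was 3.23% to 3.48% and 3.94% to 3.99% of the signal. Rows with a detection p under 0.01 numbered 10298 on the unirradiated array, 11177 and 10911 on the irradiated wild-type arrays, and 9519 and 9493 on the arrays labelled TRAF6 null. On the H1299 arrays 13674, 12716 and 14233 probes for vector, p53 wild type and K24R passed that threshold. The number of arrays limits the precision.

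Signals were background-corrected with neqc in limma 3.58.1 under R 4.3.3 with an offset of 16, then quantile-normalized and taken to log2, separately for mouse and human. The offset pulls fold changes of dim genes towards 1. For mouse, the mean and SD of the negative controls that neqc needs were estimated from the median signal at each detection p between 0.02 and 0.98. The function's own inference from the detection p-values does not suit a table in which p-values were averaged over probes. This step replaced the default for mouse after the background estimates had been seen, and the default is among the alternatives. For human, the function's own inference was used. Mouse rows with a detection p under 0.01 on at least 2 of 5 arrays were tested, 11563 in all. The averaged detection p is strict: 2813 rows with a signal above the negative controls on at least 2 arrays were left out, 44 of them with a signal over 1000 on all arrays. Human probes with a detection p under 0.01 on at least 1 array were kept, 15569 probes of 12602 genes. A human gene was represented by its probe of highest mean signal. Of these genes, 2443 had several passing probes. Among genes with several probes that reached 2-fold, the probes differed in sign for 7 of 107, 2 of 28 and 6 of 39 genes in the 3 comparisons.

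Mouse row names were updated through the gene table of the GRCm38.p6 assembly, used for names alone. Of the mouse names, 16223 matched a current symbol, 5684 a synonym and 8947 neither, and those kept the name in the table. A gene listed under both a symbol and a synonym counts once per row. Spreadsheet dates stood in place of 22 mouse names and of the names of 54 human probes, and these rows were not named.

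Mouse differences were tested with limma (lmFit, eBayes) on all 5 arrays with a mean per group, 2 residual degrees of freedom and 2.88 prior ones, two-sided, with Benjamini-Hochberg adjustment at 0.05. The unirradiated group is a single array, assumed to vary like the others. A gene not above background on any array of a group has only a bound there. For mouse, where detection p-values were averaged, above background means a signal over the 99th percentile of the negative controls (122.2 to 128), and for human a detection p under 0.01. Its ratio is printed as "at least N-fold", from the brighter group's mean against the mean over the dim group's arrays of the higher of the gene's own value and the lowest value above background. List medians are also given with such genes at their bound where this moved them by over 0.1. The 27 mouse gene lists were tested with camera at a preset inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated for each list, adjusted over the lists. The alternative takes its p-values from the 2 residual degrees of freedom and has little power here. A list that does not pass with it may therefore fail whatever its correlation. A list may also fail because its estimated correlation lies above the preset, and these reasons were not separated. The estimates were 0.17 for all p53 targets, 0.41 for interferon response and 0.31 for G1/S and replication genes. For medullary epithelium and NF-kB targets they were 0.005 and 0.05. For H1299, log2 differences, genes at or above 2-fold and list medians are given, each median with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. Bead errors printed for H1299 cover the spread of beads on these arrays and no difference between cultures.

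Fixed before the data were examined were the groups, tests, gene lists and alternatives. The lists were p53 targets for arrest and DNA repair, for apoptosis, and for feedback, metabolism and other roles, all p53 targets together, mitochondrial apoptosis machinery, NF-kB targets, interferon response, G2/M, G1/S and replication, heat shock and immediate early genes, unfolded protein and amino acid stress response, and glucocorticoid response. For thymus they also held markers of double-positive and double-negative thymocytes, mature T cells, B cells, macrophages, neutrophils, dendritic cells, medullary and cortical thymic epithelium, Aire-dependent tissue-restricted antigens, fibroblasts, endothelium, erythroid cells, adipocytes and skeletal muscle. Lists of T lineage and brown fat genes were added after the data had been seen. Genes were named by a rule: Traf6, then the 10 largest rises and falls past the threshold whose groups do not overlap, up to 4 members per list with the smallest p (H1299: the largest difference), and Cdkn1a, Mdm2, Bax, Bbc3 and Pmaip1. Predicted genes and names that are only accessions were passed over. Not all genes that the rule names are reported here.

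For the level of irradiation-responsive genes in irradiated thymus labelled TRAF6 null, 100 genes with the highest and 100 with the lowest difference on 1 irradiated wild-type array were chosen. Their level was then compared with the other wild-type array, both ways round, to keep the error of a shared array out of the difference. The alternatives were other background corrections and scalings, the authors' matrix, other detection filters, the mean of a human gene's probes, a trended and robust variance model, the replicate number as a block, only the 4 irradiated arrays, other gene numbers or fold thresholds, and each irradiated array left out. The fit was tested on simulated data for 11563 genes, with 50 genes changed at each of 4 sizes. For arrays labelled TRAF6 null against wild type it called 0 genes at 1.5-fold, 19 at 2-fold, 50 at 4-fold and 50 at 8-fold, with 14 calls among unchanged genes. For irradiation it called 0, 4, 48 and 50, with 12 among unchanged genes. In each comparison, calls among unchanged genes were a larger share of all calls than the adjustment is set to allow. Only 200 genes were changed in the simulation, while 5045 and 4186 genes passed in the data in the same order. With more genes passing, the adjusted threshold is looser, so the simulated call rates do not carry over to the data.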

Results

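The data comprise 5 arrays of mouse thymus RNA and 3 arrays of RNA from H1299 cells. In thymus, 1 array came from unirradiated wild type, 2 from wild type after 15 Gy, and 2 were labelled TRAF6 null after 15 Gy. TRAF6 is a ubiquitin ligase that relays signals of the TNF receptor and Toll-like receptor families to NF-kB. The H1299 cells had been transfected with empty vector, p53 wild type or p53 K24R, in which the lysine at residue 24 is arginine. On the mouse arrays, the correlation across genes was 0.988 between the irradiated wild-type arrays, 0.971 between the arrays labelled TRAF6 null, and 0.865 to 0.886 between groups. Genes are not independent replicates.

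The first comparison asked how irradiated thymus labelled TRAF6 null differed from irradiated wild type. The Traf6 signal, which should be lost or cut short in a null, was 2.19-fold higher on the arrays labelled TRAF6 null (log2 difference 1.13 ± 0.20 SE, limma adjusted p = 0.0123, 2 arrays against 2). Its normalized log2 signal was 8.11 on the unirradiated array, 7.67 and 7.74 on the irradiated wild-type arrays, and 9.04 and 8.62 on the arrays labelled TRAF6 null. Over other corrections and scalings the difference ranged from 0.50 to 1.19, and it did not pass without either irradiated wild-type array or with neqc's own inference of the background. The table does not say how many probes the Traf6 row averages or where they lie relative to the deletion. A loss at a single probe could be hidden in a mean over several. This signal therefore does not check the labels, and each direction given here rests on them.

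Target genes of p53, the transcription factor that DNA damage activates, were lower on the arrays labelled TRAF6 null. Of 49 tested targets, 21 were lower and 6 higher, with the same counts adjusted over the list alone (median log2 difference -0.62, limma camera adjusted p = 0.00446, and adjusted p = 0.591 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, was 2.53-fold lower (log2 -1.34 ± 0.19 SE, adjusted p = 0.00746), and Mdm2, which encodes the ligase that degrades p53, was 2.04-fold lower (-1.03 ± 0.19 SE, adjusted p = 0.0139). The targets with roles in feedback and metabolism held 10 lower and 1 higher of 18, also adjusted over the list alone (median -0.99, camera adjusted p = 0.0021, and adjusted p = 0.569 with an estimated correlation). Among them Gdf15, a secreted stress cytokine, was at least 26.4-fold lower, Tgm2, a transglutaminase, 6.68-fold lower and Gls2, a mitochondrial glutaminase, at least 2.45-fold lower. Of 16 arrest and repair targets 6 were lower and 3 higher, likewise adjusted over the list alone (median -0.83, or -0.59 with genes at their bound, camera adjusted p = 0.152). Plk3 was 3.48-fold lower, while Sesn1 and Ddb2 were 4.85-fold and 3.32-fold higher. Both arrays labelled TRAF6 null lay below both wild-type arrays for Cdkn1a and Mdm2, and neither gene passed once either irradiated wild-type array was left out. Of the 42 targets still tested, 1 lower and 2 higher passed limma's test without array 1 and no gene passed without array 2, while the list still passed camera at the preset correlation, with medians of -0.47 and -0.54. On the same arrays, double-positive thymocyte markers had a median of -0.69 that did not pass, medullary epithelial and dendritic cell markers were lower, and neutrophil, erythroid, adipocyte and fibroblast markers were higher. These 6 lists had camera adjusted p from 0.569 to 0.59 with an estimated correlation.

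Apoptosis genes were called in both directions, and neither of their lists passed camera. Of 15 p53 targets that promote apoptosis, 5 were lower and 2 higher, also adjusted over the list alone (median -0.06, camera adjusted p = 0.474). Apaf1, the core of the apoptosome, was 4.91-fold lower, Phlda3 3.20-fold lower and Zmat3 2.85-fold lower, and Siva1 was 1.55-fold higher. Bax, which permeabilises mitochondria, was 1.93-fold lower (log2 -0.95 ± 0.28 SE, limma adjusted p = 0.0481), lower on both arrays labelled TRAF6 null than on both wild-type arrays, and this call ended in several alternatives, among them no background correction and median scaling. Bbc3, which encodes the BH3-only protein PUMA, differed by -0.25 ± 0.26 SE (adjusted p = 0.467), and Pmaip1 was not tested because its averaged detection p did not pass on any mouse array. Of 16 genes of the mitochondrial apoptosis machinery, 3 were lower and 3 higher, or 2 lower and 0 higher adjusted over the list alone (median -0.12, camera adjusted p = 0.652). Htra2 was 2.94-fold and Mcl1 1.94-fold lower. Bik and Bcl2l11 were 1.53-fold and 1.44-fold higher, a direction that turned to -0.0034 and -0.0111 on the log2 scale with the authors' matrix.

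NF-kB and interferon genes were lower on the arrays labelled TRAF6 null. Medullary epithelial and dendritic cell markers were lower on the same arrays (medians -2.13 and -1.06). A changed mix of cells and a change of signalling within cells therefore cannot be told apart for these genes. Of 26 NF-kB targets 19 were lower and 1 higher, also adjusted over the list alone (median -1.69, or -1.31 with genes at their bound, limma camera adjusted p = 5.09e-05, and adjusted p = 0.569 with an estimated correlation). Relb and Nfkb2, which encode the subunits of the alternative NF-kB pathway, were 7.20-fold and at least 5.86-fold lower, Nfkbie 3.99-fold and the chemokine gene Cxcl1 12.9-fold lower. Of 24 interferon response genes 15 were lower and 1 higher, or 19 lower and 1 higher adjusted over the list alone (median -1.49, camera adjusted p = 0.000236, and adjusted p = 0.59 with an estimated correlation). Usp18 was 14.5-fold lower, Irf7 10.8-fold lower and Oas2 at least 9.90-fold lower.

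Medullary thymic epithelial cells, which display tissue antigens to developing T cells, had the lowest list median. Of their 16 markers 12 were lower and 1 higher, or 13 and 1 adjusted over the list alone (median -2.13, or -1.77 with genes at their bound, camera adjusted p = 4.24e-05, and adjusted p = 0.569 with an estimated correlation). Fezf2, a transcription factor of these cells, was 44.6-fold lower in its entry under a former name and at least 8.98-fold lower in the other, Aire, their regulator of tissue antigens, at least 8.71-fold lower and Tnfrsf11a, which encodes the receptor RANK, 7.31-fold lower. Of 23 entries of Aire-dependent antigens 13 passed the detection filter, and all 13 were lower, also adjusted over the list alone (median -1.87, or -0.98 with 12 genes at their bound, camera adjusted p = 3.41e-07, and adjusted p = 0.569 with an estimated correlation). They included Csn2, Spink1, Fabp9 and Apoa1, at least 24-fold, 22.1-fold, 14.6-fold and 7.57-fold lower. The 12 genes at their bound were not above background on the arrays labelled TRAF6 null. The filter thus favoured antigens that were high on wild-type arrays, and the count of 13 is partly fixed by it. Dendritic cell markers held 7 lower and 0 higher of 12, or 9 and 0 adjusted over the list alone (median -1.06, camera adjusted p = 0.015, and adjusted p = 0.569 with an estimated correlation), with Fscn1 24.3-fold, Batf3 2.74-fold and Irf8 2.22-fold lower. Batf3 has a further entry, whose value is not given here. With median scaling the dendritic cell list no longer passed.

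Replication genes and markers of several other cell types were higher on the arrays labelled TRAF6 null. Of 22 G1/S and replication genes 15 were higher and 0 lower, or 16 and 0 adjusted over the list alone (median 1.04, limma camera adjusted p = 4.24e-05, and adjusted p = 0.569 with an estimated correlation). Gins2, which has a further entry not given here, was 4.09-fold, Rfc4 3.40-fold and Mcm6 3.29-fold higher. Of 16 G2/M genes 3 were higher and 2 lower, also adjusted over the list alone (median 0.03, camera adjusted p = 0.774), with Birc5 3.31-fold higher and Plk1 2.72-fold lower. Neutrophil and myeloid precursor markers held 7 higher and 1 lower of 12, also adjusted over the list alone (median 1.98, or 1.81 with genes at their bound, camera adjusted p = 0.00494, and adjusted p = 0.59 with an estimated correlation), with Chil3 9.69-fold and Mpo 3.61-fold higher. Erythroid markers held 7 higher and 0 lower of 12, also adjusted over the list alone (median 1.62, camera adjusted p = 0.00259, and adjusted p = 0.569 with an estimated correlation), with the anion exchanger gene Slc4a1 15.1-fold higher. Adipocyte markers held 6 higher and 0 lower of 8, also adjusted over the list alone (median 1.67, camera adjusted p = 0.00556, and adjusted p = 0.569 with an estimated correlation), with Cidea 7.10-fold and Adipoq 4.54-fold higher. Fibroblast markers held 6 higher and 1 lower of 13, also adjusted over the list alone (median 0.71, camera adjusted p = 0.00926, and adjusted p = 0.569 with an estimated correlation), with Lum 12.8-fold and Pdgfra 3.35-fold higher.

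Thymocyte markers, from the main cell type of the organ, did not pass as lists. Double-positive thymocyte markers held 4 lower and 1 higher of 14, also adjusted over the list alone (median -0.69, camera adjusted p = 0.0962), with Tcf7 1.64-fold lower. Cd8b1 has 2 entries, 3.15-fold lower in the first and -0.92 in log2 in the second, which did not pass. Double-negative markers held 3 lower and 1 higher of 9, also adjusted over the list alone (median -0.41, camera adjusted p = 0.152), with Notch3 3.29-fold and Notch1 2.71-fold lower. Without irradiated wild-type array 2 the double-positive list passed with camera, and arrest and repair targets passed without array 2 labelled TRAF6 null.

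In all, 5045 of 11563 genes passed limma's test between these groups, 2404 higher and 2641 lower on the arrays labelled TRAF6 null, of which 1361 and 1652 differed by 2-fold or more. The largest rise was that of Depp1, a FOXO target, at 48.2-fold, followed by Ctla4, an inhibitory receptor of T cells, at 20.4-fold. The largest falls outside the lists included the epidermal genes Sprr2d and Lor, at least 23.8-fold and 20.7-fold lower. The count depends on the wild-type pair: gene calls within the lists fell with it, and it was 688 without irradiated wild-type array 1 and 53 without array 2 (3678 and 3452 at an unadjusted p under 0.05), and 2951 with neqc's own inference of the background. Without an irradiated wild-type array, the spread comes from the pair labelled TRAF6 null alone, which agreed less closely (correlation 0.971, against 0.988 for wild type), so fewer genes can pass. With the authors' matrix the split was 1247 higher and 4390 lower, where the median log2 difference of all genes was -0.28 in place of -0.03. It went the other way with median scaling (3061 higher and 2299 lower) and with detection on all 5 arrays (1902 and 1530), so the split has no settled direction.

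**Figure D1:**
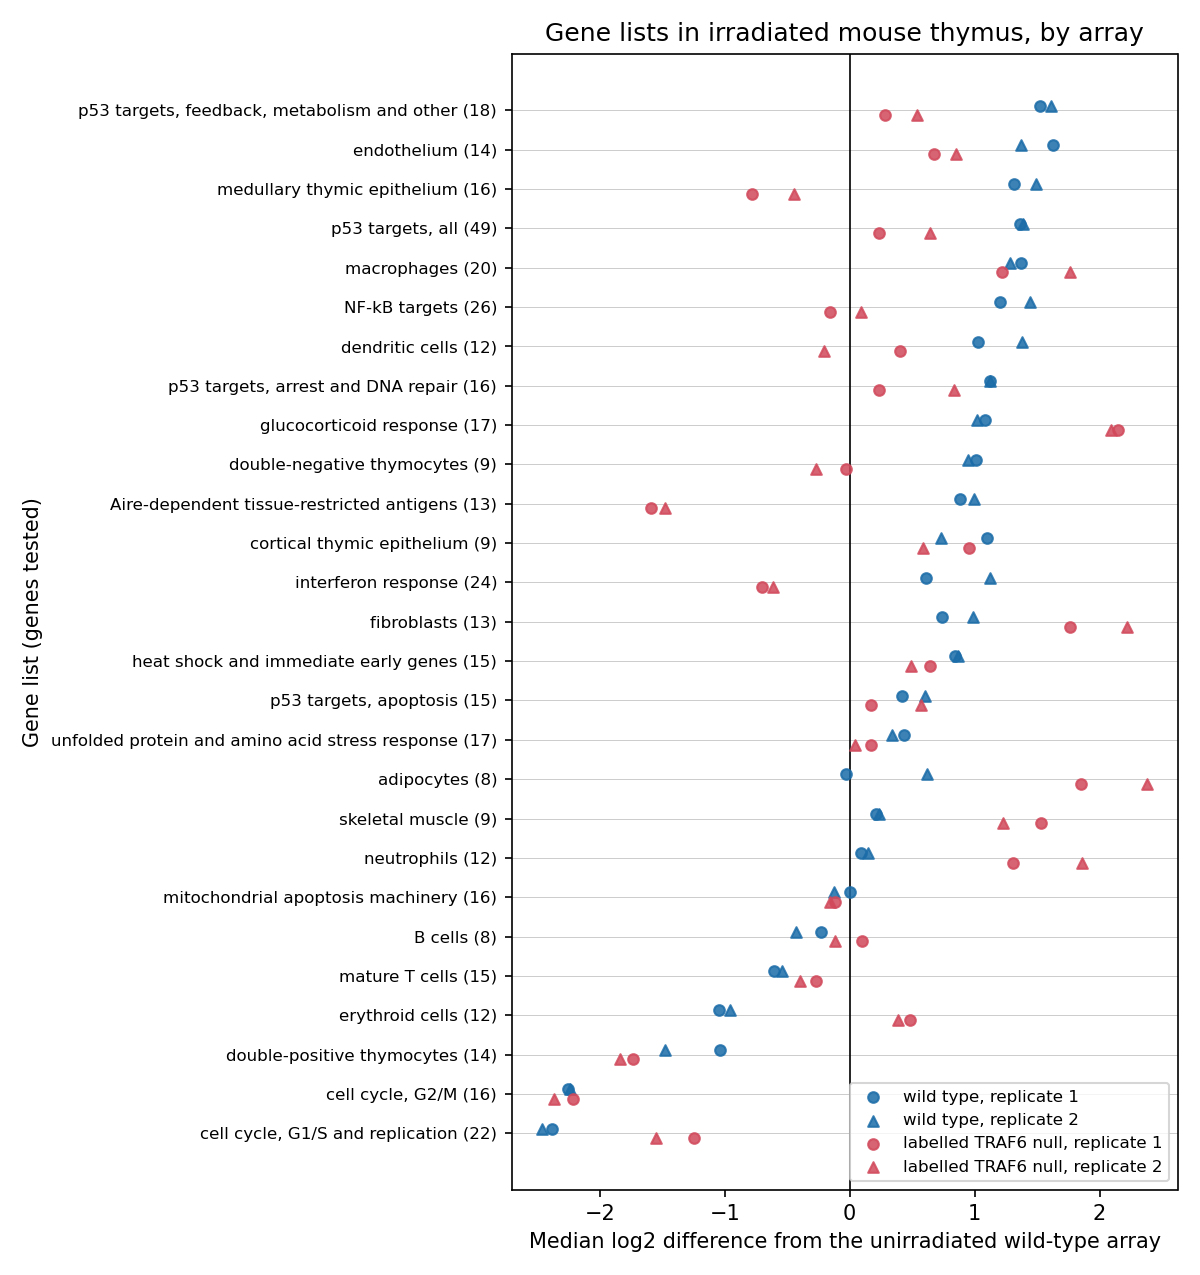
Median log2 difference of each gene list from the unirradiated wild-type array, for each of the 4 irradiated mouse arrays. Each point is 1 array, and the medullary epithelium and NF-kB points of wild type lie above those of the arrays labelled TRAF6 null, while the G2/M medians lie at -2.25 for wild type and -2.26 for the arrays labelled TRAF6 null.

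The second comparison asked what irradiation did in wild-type thymus, with 2 irradiated arrays against 1 unirradiated array. The irradiated wild-type arrays enter this comparison and the first with opposite signs. The RNA came from thymus, and thymocyte genes were lower after irradiation. All 18 genes of the added T lineage list were lower (median -1.15), and double-positive markers had a median of -1.27. For each list of this comparison, a changed mix of cells and a change within cells therefore cannot be told apart. The size of the median log2 difference of the p53 targets depended on the processing. It was 1.44 in the main setting, 0.81 without background correction, 0.54 over 67 targets without a detection filter, and 0.35 with neqc's own inference of the background. Of 49 p53 targets 26 rose and 6 fell, or 28 and 6 adjusted over the list alone (median log2 difference 1.44, limma camera adjusted p = 0.000246, and adjusted p = 0.515 with an estimated correlation). Cdkn1a rose 12.5-fold (3.65 ± 0.23 SE, adjusted p = 0.00606), Mdm2 3.44-fold (1.78 ± 0.23 SE, adjusted p = 0.00933), Bax 4.88-fold (2.29 ± 0.34 SE, adjusted p = 0.0115) and Bbc3 5.50-fold (2.46 ± 0.32 SE, adjusted p = 0.00915). The Traf6 signal differed by -0.40 (adjusted p = 0.247). Feedback and metabolism targets held 13 rises and 0 falls of 18, also adjusted over the list alone (median 1.5, camera adjusted p = 3.35e-05, and adjusted p = 0.465 with an estimated correlation), with Gdf15 at least 29.2-fold, Tgm2 20-fold and Dcxr 7.37-fold higher. Arrest and repair targets held 7 rises and 4 falls of 16, or 9 and 4 adjusted over the list alone (median 1.12, or 0.96 with genes at their bound, camera adjusted p = 0.129). Plk3 rose 6.77-fold, while Pcna, the replication clamp and also a p53 target, fell 9.08-fold. Apoptosis targets held 6 rises and 2 falls of 15, also adjusted over the list alone (median 0.51, or 0.33 with genes at their bound, camera adjusted p = 0.195), with Phlda3 8.34-fold and Zmat3 5.72-fold higher and Bid 3.26-fold lower. The mitochondrial apoptosis machinery held 3 rises and 2 falls of 16, and 0 of either adjusted over the list alone (median -0.09, mean 0.07, camera adjusted p = 0.919).

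**Figure D2:**
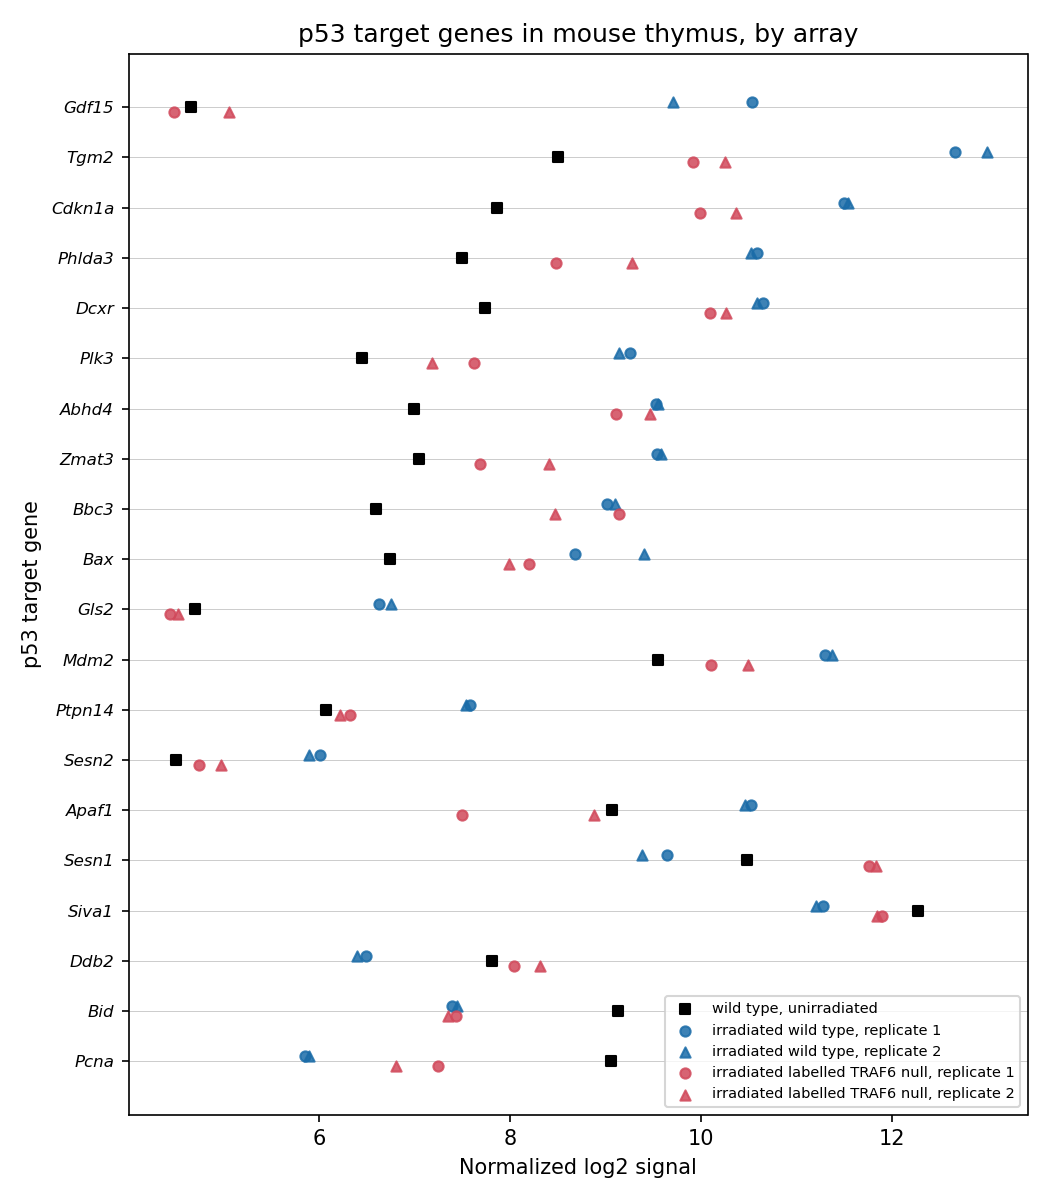
Normalized log2 signal of 20 p53 target genes on each of the 5 mouse arrays, 1 point per array. Cdkn1a lies at 7.87 on the unirradiated array, at 11.5 on both irradiated wild-type arrays, and at 9.99 and 10.4 on the arrays labelled TRAF6 null.

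Cell cycle genes fell after irradiation. Of 16 G2/M genes 13 fell and 0 rose, or 14 and 0 adjusted over the list alone (median -2.25, limma camera adjusted p = 4.05e-07, and adjusted p = 0.381 with an estimated correlation), with Ccnb1 14.7-fold and Kif11 14.4-fold lower. Of 22 G1/S and replication genes 20 fell and 0 rose, or 21 and 0 adjusted over the list alone (median -2.39, camera adjusted p = 1.93e-11, and adjusted p = 0.46 with an estimated correlation), with Tyms 15.3-fold and Rfc4 9.84-fold lower. Double-positive thymocyte markers held 7 falls and 2 rises of 14, or 8 and 2 adjusted over the list alone (median -1.27, camera adjusted p = 0.0087, and adjusted p = 0.515 with an estimated correlation). Themis and Ptcra, both needed in T cell development, were 14.3-fold and 3.32-fold lower. Erythroid markers held 5 falls and 0 rises of 12, also adjusted over the list alone (median -1.08, camera adjusted p = 0.0106, and adjusted p = 0.476 with an estimated correlation).

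NF-kB targets and markers of macrophages, endothelium, dendritic cells, medullary epithelium and fibroblasts rose. Of 26 NF-kB targets 16 rose and 0 fell, or 20 and 0 adjusted over the list alone (median 1.44, or 1.23 with genes at their bound, limma camera adjusted p = 9.15e-06, and adjusted p = 0.381 with an estimated correlation). Ier3 was 24.3-fold and the chemokine gene Ccl2 at least 16.2-fold higher. Macrophage markers held 15 rises and 0 falls of 20, or 17 and 0 adjusted over the list alone (median 1.32, camera adjusted p = 3.39e-06, and adjusted p = 0.518 with an estimated correlation), with Cd14 9.10-fold and Cd68 6.39-fold higher. Endothelial markers held 10 rises and 0 falls of 14, or 11 and 0 adjusted over the list alone (median 1.57, or 1.47 with genes at their bound, camera adjusted p = 3.22e-05, and adjusted p = 0.381 with an estimated correlation), with Plvap 8.16-fold higher. Dendritic cell markers held 8 rises and 0 falls of 12, also adjusted over the list alone (median 1.26, camera adjusted p = 0.000716, and adjusted p = 0.381 with an estimated correlation). Medullary epithelial markers held 9 rises and 1 fall of 16, or 10 and 1 adjusted over the list alone (median 1.40, camera adjusted p = 0.000716, and adjusted p = 0.381 with an estimated correlation). Aire-dependent antigens held 8 rises and 0 falls of 13, also adjusted over the list alone (median 0.94, camera adjusted p = 0.00733, and adjusted p = 0.515 with an estimated correlation). Fibroblast markers held 7 rises and 1 fall of 13, or 8 and 1 adjusted over the list alone (median 0.80, camera adjusted p = 0.0126, and adjusted p = 0.515 with an estimated correlation). Interferon response genes held 5 rises and 1 fall of 24, or 3 and 1 adjusted over the list alone (median 0.98, camera adjusted p = 0.0181, and adjusted p = 0.575 with an estimated correlation), and this list did not pass with the authors' matrix.

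In all, 4186 genes passed limma's test for irradiation, 2156 higher and 2030 lower. The largest rises were those of the chemokine gene Ccl3, at least 41.7-fold, Gdf15, at least 29.2-fold, and the chemokine gene Ccl7, 41.4-fold, and the largest falls those of Trat1, a T cell receptor adaptor, 28.2-fold, and Dntt, the polymerase that diversifies antigen receptors, 20.9-fold. The count was 0 without either irradiated wild-type array (3391 without array 1 and 3124 without array 2 at an unadjusted p under 0.05), 6293 without array 2 labelled TRAF6 null, and 2763 with neqc's own inference of the background (1138 higher and 1625 lower). With the authors' matrix 3392 genes were higher and 1484 lower, with a median of all genes of 0.26 in place of 0.05.

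The third comparison set irradiated thymus labelled TRAF6 null against unirradiated wild type. Genotype label and irradiation differ together in it, because no unirradiated TRAF6 null sample is among those analysed here, so it is descriptive. The p53 targets had a median log2 difference of 0.37, with 13 of 49 higher and 3 lower, also adjusted over the list alone (limma camera adjusted p = 0.0193, and adjusted p = 0.611 with an estimated correlation). The median was 0.66 without array 1 labelled TRAF6 null and 0.24 without array 2. In irradiated wild type the median over the same list was 1.44. Medians of NF-kB targets and medullary epithelial markers were -0.08 (mean 0.03) and -0.44, and that of G2/M genes -2.26.

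To follow the irradiation-responsive genes, sets were chosen on 1 irradiated wild-type array and measured against the other. The 100 genes that rose most on array 1 lay 3.30 log2 units above the unirradiated level on wild-type array 2, and 1.94 above it on the arrays labelled TRAF6 null. The median difference between these was -1.52, and -1.60 with the wild-type arrays exchanged, with 17 and 16 of 100 genes higher on the arrays labelled TRAF6 null. The 100 genes that fell most lay 3.20 below the unirradiated level on the other wild-type array and 1.92 below it on the arrays labelled TRAF6 null. Their median difference was 1.49, and 1.15 with the arrays exchanged, with 92 and 90 of 100 genes higher on the arrays labelled TRAF6 null. With the authors' matrix the mean of both ways was 0.70 in place of 1.32 for the genes that fell. These values have no test, and the unirradiated level comes from 1 array. The sets were extremes of wild type, and none was chosen on the arrays labelled TRAF6 null. A smaller difference on the latter is thus partly built in, and the values do not show a weaker response.

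In H1299 cells, the question was how p53 K24R compares with p53 wild type as an activator of target genes, with 1 array each and so no replicate check. The labels of these arrays were not checked here, and each direction rests on them. Both p53 forms went with higher target genes. With p53 wild type, the 56 measured targets had a median log2 difference of 0.56 from vector, above all 10000 matched random lists (percentile 100), with 41 higher, 19 of them at least 2-fold. With K24R the median was 0.45, or 0.40 with genes at their bound (percentile 100), with 46 higher and 12 at 2-fold. GDF15 was 68.8-fold higher with p53 wild type and 32.8-fold with K24R, TP53I3, an oxidoreductase induced in apoptosis, 22.1-fold and 13.2-fold, and CDKN1A 6.28-fold and 3.92-fold (log2 2.65 and 1.97, with 4.17 and 3.83 for its other probe). MDM2 was at least 1.92-fold and 2.03-fold higher, and BAX 2.65-fold and 1.41-fold. BBC3 differed by -0.13 ± 0.21 and 0.18 ± 0.19, and PMAIP1 by 0.04 ± 0.25 and 0.10 ± 0.26 (bead errors).

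By role, the p53 wild-type medians were 0.53 for 18 arrest and repair targets, 0.45 for 16 apoptosis targets and 0.63 for 22 feedback and metabolism targets, at percentiles 99.99, 100 and 100. The K24R medians were 0.42, 0.46 and 0.50, all at percentile 100, and the last was 0.35 with genes at their bound. Directly compared, K24R minus p53 wild type gave -0.13 over the 56 targets (percentile 1.31), with 26 higher and 30 lower. It turned to 0.03 with the authors' matrix, where the median of all genes was 0.09 in place of 0.02. The medians by role were -0.04, 0.05 and -0.28 in the same order, at percentiles 31.4, 63.2 and 0.19. GDF15 was 2.10-fold, FDXR, a mitochondrial reductase, 2.78-fold, PLK3 2.49-fold, DDB2 2.15-fold, BAX 1.88-fold and CDKN1A 1.60-fold lower with K24R (log2 -0.68, with -0.34 for the other CDKN1A probe), while MDM2 differed by 0.08 ± 0.17 (bead error).

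The G2/M genes separated the 2 forms. All 27 were lower with p53 wild type than with vector (median -0.88, percentile 0), 21 of 27 were lower with K24R (median -0.26, percentile 0), and all 27 were higher with K24R than with p53 wild type (median 0.68, percentile 100). TOP2A was 3.55-fold lower with p53 wild type and 1.64-fold lower with K24R, and CCNB1 was 2.10-fold higher with K24R than with p53 wild type. G1/S and replication genes had medians of -0.26 (percentile 0.1), -0.12 (percentile 3.64) and 0.33 (percentile 99.99) in the same order, with MCM10 1.85-fold lower with p53 wild type than with vector.

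**Figure D3:**
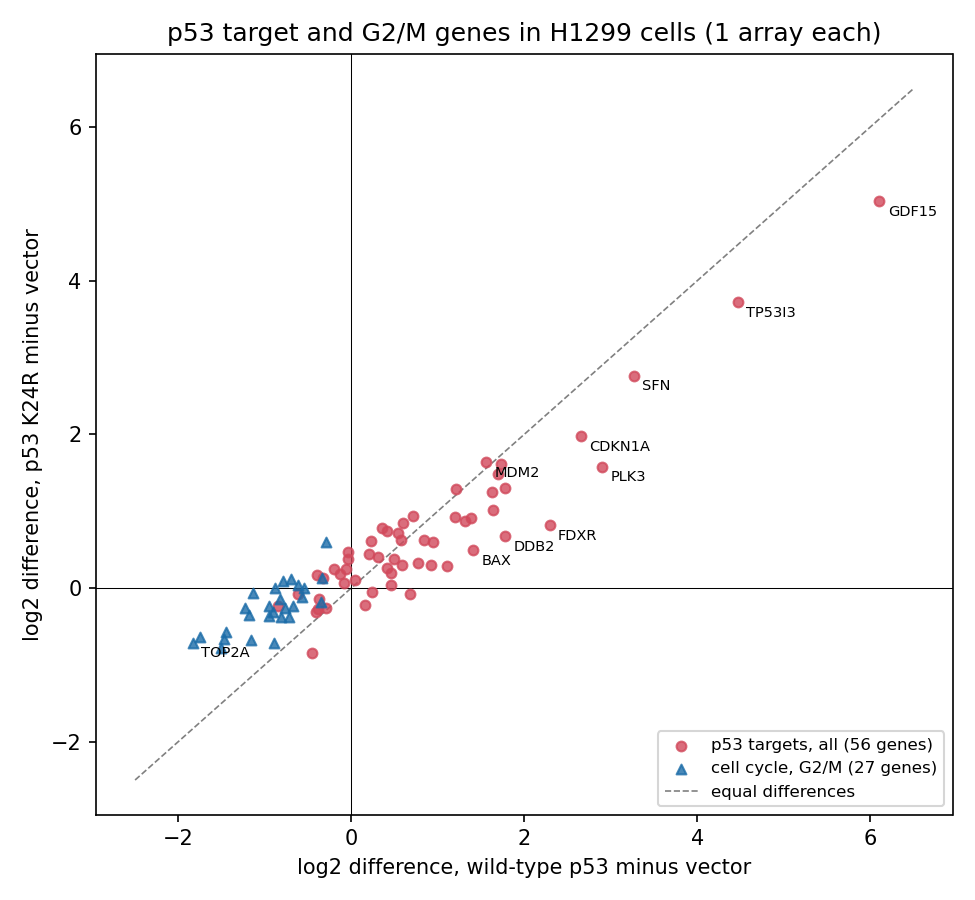
Log2 difference from vector with p53 wild type (horizontal) and with p53 K24R (vertical) for 56 p53 targets and 27 G2/M genes, 1 point per gene, from 1 array per condition. The dashed line marks equal differences, and all 27 G2/M genes lie above it.

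Genes at or above 2-fold numbered 643 for p53 wild type against vector (350 higher, 293 lower), 259 for K24R against vector (175 and 84) and 360 for K24R against p53 wild type (148 and 212). Of these 275, 76 and 131 were detected on both arrays. Beside the targets named above, DPYSL4 and CRYAB, a small heat shock protein gene, were at least 12.4-fold and 9.62-fold higher with p53 wild type, and at least 9.64-fold and 4.99-fold higher with K24R. The receptor gene FGFR3 was 11.1-fold higher with p53 wild type and 18.6-fold higher with K24R, and SUSD2 at least 5.41-fold and 10.2-fold higher. Between the 2 forms UNC5A, a netrin receptor gene, was at least 4.96-fold higher with K24R, and DTL, which encodes a replication-linked ubiquitin ligase subunit, at least 2.74-fold higher. The counts fell to 82, 38 and 11 without background correction, with 64 and 18, 37 and 1, and 3 and 8 higher and lower. With median scaling the split was 433 higher and 219 lower for p53 wild type against vector and 87 and 277 for K24R against p53 wild type, so the share of higher genes has no settled value.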

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

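Of the tests in this part, those on exchanged labels, thymocytes (T lineage and double-positive), exposure, share of thymocytes and brown fat were chosen only after the result was seen, while those on scaling were chosen before, except for limma's own inference of the background, which was added after. In 5 gene lists, both irradiated wild-type arrays moved one way from the unirradiated array and both arrays labelled TRAF6 null moved the opposite way. All share 1 unirradiated wild-type array, and the difference between the groups is the median given here with its camera test. It was -2.131 for medullary thymic epithelium (limma camera adjusted p = 4.24e-05, and adjusted p = 0.569 with an estimated correlation). For Aire-dependent antigens, 12 of 13 at their bound and favoured by the detection filter where high in wild type, it was -1.869 (camera adjusted p = 3.41e-07, and adjusted p = 0.569 with an estimated correlation). For interferon response genes it was -1.494 (camera adjusted p = 0.000236, and adjusted p = 0.59 with an estimated correlation). Erythroid markers had 1.624 (adjusted p = 0.00259, and adjusted p = 0.569 with an estimated correlation). Double-negative thymocyte markers had -0.4126 and did not pass (adjusted p = 0.152).

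The Traf6 signal was higher on the arrays labelled TRAF6 null, by a log2 difference of 1.13. Exchanged genotype labels are argued against by the medullary epithelium list, whose genes depend on signalling through TRAF6 and whose median was -2.131 on the arrays labelled TRAF6 null. Scaling stays open, since the difference ranged from 0.4981 to 1.1923 over the other corrections and scalings, with an adjusted p of up to 0.0712, reached with the added inference. Transcription from the targeted locus beyond the deletion also stays open and was not tested, since the number and position of the averaged probes are not given.

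The p53 targets were lower on the arrays labelled TRAF6 null, with a median of -0.62. Scaling is argued against: the median was -0.3844 to -0.6004 over the planned corrections and scalings and -0.2049 with the added inference, with camera adjusted p at or below 0.0348 at the preset correlation (adjusted p = 0.591 with an estimated correlation in the main setting). Fewer thymocytes stay open, since 14 T lineage genes had a median 0.9137 above that of the p53 targets (bootstrap interval over genes 0.1939 to 1.4404), while double-positive thymocyte markers differed from the p53 targets by -0.0714 (bootstrap interval -0.5865 to 0.6164), with 11 of 14 lower, and double-negative markers had -0.41. Weaker exposure to radiation stays open, and the cell cycle lists differ on it. The 16 G2/M genes, which fell after irradiation, differed between the groups by 0.0292 (bootstrap interval -0.3597 to 0.5446), a median over members that went both ways. The 22 G1/S and replication genes also fell after irradiation (median -2.39). They lay 1.04 higher on the arrays labelled TRAF6 null, with 15 higher and 0 lower, and no such interval was computed for them. A role of TRAF6 in the p53 response and an effect of genotype before irradiation also stay open and were not tested, because no unirradiated TRAF6 null sample is among those analysed here, and other causes upstream of the target genes were not weighed.

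Erythroid, neutrophil, adipocyte and fibroblast genes were higher on the arrays labelled TRAF6 null, with medians of 1.62, 1.98, 1.67 and 0.71. A lower share of thymocytes would raise the markers of every other cell type if those cells were otherwise unchanged. Macrophage, endothelial and B cell genes did not rise with the others: their pooled median over 42 genes was -0.2213 (bootstrap interval over genes -0.4431 to 0.1541). A fall of their own could hide such a rise, and of the macrophage markers 8 were higher and 12 lower, so a lower share stays open. For the adipocyte part, brown fat taken along with the thymus stays open: 9 brown fat genes that are in no other list and were not named had a median of 1.621 (bootstrap interval 0.8253 to 1.8993), with only 3 of them higher and 1 lower past the threshold. Changes in these cell types in the thymus of mice lacking TRAF6 also stay open and were not tested.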

How the results depend on the processing

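All p-values rest on 2 arrays or 1 array per group, and genes near background carry compressed differences. A tested result past its threshold in neither setting counts here as keeping its side, and a turn of direction counts only where a setting passes. Lone arrays after leaving an array out were assumed to vary like the other groups. Without an irradiated wild-type array, the spread came from the pair labelled TRAF6 null alone, which agreed less closely than the wild-type pair, so fewer genes could pass in either comparison. Not run were a slide block (no slide is given), the mean of probes for mouse (1 row per gene), other splits of the samples (no group of 3), a search for outlying arrays (no group of 4), and the sets of irradiation-responsive genes without an irradiated wild-type array. The labels do not say what the replicate numbers mark. Deviations from the group means correlated at 0.032 across genes between irradiated arrays with the same number. No large shared effect was thus seen, while a smaller one is not excluded. With the replicate block 4972 genes passed between the arrays labelled TRAF6 null and wild type (5045 without) and 4033 for irradiation (4186). The inference of background by limma and a filter on signal were added after the data had been seen. For other values that moved, the cause was not tested.

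Of the tested mouse list results over all alternatives, 812 kept their side of the threshold, 37 lost the call (28 of them with an estimated correlation), 13 gained it, and none turned. Of the named mouse gene results 2797 kept their side, 509 lost the call (164 and 199 of them without irradiated wild-type array 1 and 2), 12 gained it, and 2 turned: Bik to -0.0034 and Bcl2l11 to -0.0111 with the authors' matrix. For H1299, 179 list values stayed near the main value, 79 moved and 1 turned, and for named genes 811 stayed and 491 moved.

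With an estimated correlation, 0 of 27 lists passed in either tested mouse comparison by limma camera (13 and 15 with the preset), with the p53 targets at -0.6162 (adjusted p = 0.591) and 1.439 (adjusted p = 0.515). With limma's own inference of negative controls 2951 and 2763 genes passed. Leaving out 1 array gave 53 (without irradiated wild-type array 2; 688 without array 1) to 5856 genes between the genotype labels and 0 (without either irradiated wild-type array, where 3391 and 3124 had an unadjusted p under 0.05) to 6293 for irradiation. The p53 targets in irradiated thymus labelled TRAF6 null against unirradiated wild type ranged from 0.2427 to 0.6574 with an array left out.

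For irradiation-responsive genes, the difference for those that rose was -1.719 with 50 genes, -1.392 with 200 and -1.27 to -1.933 with an array labelled TRAF6 null left out. Without background correction it was -1.198 (0.9992 for those that fell), and with the authors' matrix -1.408 (0.7014).

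In H1299, genes past the fold threshold for p53 wild type against vector, K24R against vector and K24R against p53 wild type numbered 643, 259 and 360. At 1.5-fold they were 2604, 1598 and 2286, without background correction 82, 38 and 11, with saddle-point correction 130, 57 and 28, with the authors' matrix 69, 33 and 10, and with detection on all 3 arrays 275, 74 and 121. Shares of higher genes were 54.4%, 67.6% and 41.1%, and 71%, 100% and 60% with the authors' matrix. The p53 target medians against vector, 0.56 and 0.45, were 0.3942 and 0.3047 without background correction, 0.4456 and 0.3603 with saddle-point correction, 0.3149 and 0.291 with the matrix, and 0.3116 and 0.3205 without a filter. With median scaling the p53 wild-type median was 0.7, and with detection on all 3 arrays the K24R median was 0.3902. K24R against p53 wild type gave -0.2374 with median scaling, -0.03905 with detection on all 3 arrays, and turned to 0.02947 with the matrix.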

Other observations

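Glucocorticoid response genes, which stress hormones induce and which accompany loss of thymocytes, were higher on the arrays labelled TRAF6 null. Of 17 tested genes 8 were higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.88, limma camera adjusted p = 0.00412, and adjusted p = 0.569 with an estimated correlation). The transcription factor gene Klf9 was 4.24-fold, Txnip, a brake on glucose uptake, 3.32-fold and Zbtb16 3.16-fold higher, and Cdkn1c 3.54-fold lower. Klf9 has a further entry, whose value is not given here. Irradiation of wild type raised 9 and lowered 0, or 10 and 1 adjusted over the list alone (median 1.07, camera adjusted p = 0.0095, and adjusted p = 0.515 with an estimated correlation), with the metallothionein gene Mt1 14-fold, Errfi1 6.64-fold and Sgk1 4.37-fold higher. Heat shock and immediate early genes held 5 lower and 2 higher of 15 on the arrays labelled TRAF6 null, also adjusted over the list alone (median -0.19, camera adjusted p = 0.474), with the chaperone gene Hsph1 4.22-fold lower. After irradiation 8 rose and 3 fell of 15, also adjusted over the list alone (median 0.86, camera adjusted p = 0.128), with Atf3 at least 8.40-fold and Junb 4.84-fold higher. Of 17 genes of the unfolded protein and amino acid stress response 4 were higher and 3 lower on the arrays labelled TRAF6 null, also adjusted over the list alone (median -0.08, mean 0.04, camera adjusted p = 0.851), and after irradiation 3 rose and 2 fell (median 0.43, camera adjusted p = 0.289), with Phgdh, of serine synthesis, 2.72-fold higher and 5.55-fold lower respectively.

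Other cell types showed few differences between the genotype labels as lists. Macrophage markers held 5 lower and 3 higher of 20, or 4 and 2 adjusted over the list alone (median -0.23, limma camera adjusted p = 0.851), with Cd14 2.87-fold lower and Csf1r 2.55-fold higher. Endothelial markers held 5 lower and 2 higher of 14, also adjusted over the list alone (median -0.44, or -0.31 with genes at their bound, camera adjusted p = 0.202), with Eng 3.60-fold lower and Emcn 4.05-fold higher. Mature T cell markers held 4 higher and 3 lower of 15, or 5 and 3 adjusted over the list alone (median -0.27, mean 0.29, or a median of -0.14 with genes at their bound, camera adjusted p = 0.948), with the costimulatory receptor gene Cd28 4.22-fold higher. After irradiation 5 fell and 3 rose of 15, also adjusted over the list alone (median -0.54, camera adjusted p = 0.217). B cell markers held 2 higher and 2 lower of 8 (median 0.23, camera adjusted p = 0.465), with Cd79b 4.27-fold higher, and after irradiation 2 fell (median -0.31, camera adjusted p = 0.186). Cortical epithelial markers held 2 higher and 2 lower of 9 (median -0.18, camera adjusted p = 0.797), with Krt8 2.39-fold lower. After irradiation 5 rose and 1 fell of 9, or 6 and 1 adjusted over the list alone (median 0.91, camera adjusted p = 0.0613). Skeletal muscle markers held 4 higher and 2 lower of 9, or 6 and 2 adjusted over the list alone (median 0.91, camera adjusted p = 0.152), with Atp2a1 5.30-fold higher.

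The remaining markers after irradiation were mixed. Double-negative thymocyte markers held 4 rises and 2 falls of 9, or 5 and 2 adjusted over the list alone (median 1.09, limma camera adjusted p = 0.289), with Hes1, a Notch target, 3.84-fold higher. Neutrophil markers held 2 rises and 1 fall of 12, or 2 and 0 adjusted over the list alone (median 0.21, camera adjusted p = 0.854), with Mmp9 5.42-fold higher. Adipocyte markers held 2 rises and 0 falls of 8, also adjusted over the list alone (median 0.29, camera adjusted p = 0.324), and muscle markers 2 rises and 1 fall of 9 (median 0.22, camera adjusted p = 0.497).

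In H1299 the medians for p53 wild type against vector, K24R against vector and K24R against p53 wild type follow, from 1 array each. For 17 heat shock and immediate early genes they were 0.52, 0.47 and 0.12 (percentiles 100, 100 and 89.5), with ATF3 3.53-fold and 2.02-fold above vector. For 23 interferon response genes they were 0.22, -0.17 and -0.29 (percentiles 98.6, 2.30 and 0.13), with the ubiquitin-like gene ISG15 4.45-fold and 2.57-fold above vector. For 17 genes of the mitochondrial apoptosis machinery they were 0.31, 0.05 and -0.19 (percentiles 99.9, 80.1 and 4.90), with BAK1 1.81-fold and 1.45-fold above vector. For 15 NF-kB targets they were 0.18, -0.002 and -0.24 (percentiles 93.0, 56.4 and 3.31). For 15 genes of the unfolded protein and amino acid stress response they were 0.10, -0.02 and -0.09 (percentiles 86.6, 48.8 and 24.2), and for 12 glucocorticoid response genes 0.16, 0.004 and -0.12 (percentiles 92.8, 57.9 and 16.8).

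Lists added after the data had been seen gave a median of 0.30 for 18 T lineage genes between the arrays labelled TRAF6 null and wild type (4 higher and 2 lower, limma camera adjusted p = 0.452) and 1.65 for 13 brown fat genes (7 higher and 1 lower, camera adjusted p = 0.00163, and adjusted p = 0.741 with an estimated correlation). Against the 1 unirradiated array, the T lineage median was -1.15 in irradiated wild type and -1.32 on the arrays labelled TRAF6 null. The brown fat median was 0.86 and 2.52 in the same order. Ucp1, the uncoupling protein of brown fat, had log2 signals of 7.55 on the unirradiated array, 5.63 and 8.12 on the irradiated wild-type arrays, and 9.37 and 10.94 on the arrays labelled TRAF6 null.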
